A study of Mus musculus with 24 samples.

How the data were processed

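Poly-A RNA of E14TG2a mESCs of the 129/Ola strain was sequenced in 24 strand-specific libraries of 50 bp reads, 3 in each of 8 groups. Per the labels the cells grew feeder-free in serum and LIF. The mESC groups are untransfected cells and cells transfected with shNMC, shMed12, shCdk8 or shRing1b. The RA groups are cells with shNMC, shMed12 or shCdk8 after 24 h in 1e-06 M all-trans RA without LIF. No RA group exists for shRing1b, and the labels do not give the number of hairpin sequences or clones per target. The deposited values are raw read counts per gene symbol, 1 file per library, with no scaling. Per the submitters' processing notes the tools were bcl2fastq 1.8.4, STAR 2.3.1z13, SAMtools 1.2, HTSeq 0.6.1p1 and DESeq2 1.6.3, with genome build mm9. The notes give no roles for them, and the annotation and the strand setting of the counting are not given in the sources used here. The series text also speaks of shZrf1 cells and of an untransfected control after RA, for which there are no count files, so they are not analysed here.

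Each file holds 22609 gene symbols and 5 entries that name no gene, of which 19916 symbols had a count in at least 1 library. Gene counts per library were 27.4 to 34.1 M in the 6 untransfected and shRing1b libraries and 37.8 to 57.3 M in the other 18. Of all entries, reads with several alignments made 20.0% to 21.7% in the 6 and 44.1% to 49.1% in the 18. Reads in no annotated feature made 14.5% to 17.3% and 8.70% to 10.8%, and ambiguous reads 0.179% to 0.197% and 0.111% to 0.127%. These entries were left out of library sizes. Genes detected numbered 16848 to 18228, and the 10 most abundant genes took 3.10% to 3.77% of gene counts. A floor of 3 counts stood for 0.0523 to 0.109 CPM. Replicates of a group differed by more than counting noise in every pair (mean chi-square per gene 7.17 to 126), so the spread between libraries and not the depth sets the precision of abundant genes.

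Counts were modelled with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, which kept 16280 genes, TMM scaling, robust dispersion (common biological coefficient of variation 0.145) and a quasi-likelihood F test on 1 mean per group over all 24 libraries (16 residual degrees of freedom). Tests are two-sided, with the Benjamini-Hochberg adjusted p under 0.05 called within each comparison. Log2 changes carry edgeR's prior count, and the SE is the change divided by the square root of F. CPM means with SD use TMM-scaled library sizes. The comparisons were each hairpin against shNMC in the same state, RA against mESCs in shNMC cells, shNMC against untransfected cells, and the difference of hairpin effects between states as an interaction term. The groups, comparisons, gene lists and alternatives were fixed before the data were examined, except where the text says otherwise. The interaction of a set of RA-induced genes was tested with camera and fry of limma 3.58.1 on genes defined in a line that takes no part in that interaction. Overlaps of calls were compared with 100 simulated sets in which the hairpin groups hold no change and share their controls.

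In all 23 gene lists of textbook membership were tested by camera with a preset inter-gene correlation of 0.01, and again with an estimated one, over 9 comparisons (207 tests, adjusted together). They are Mediator kinase module, Mediator core, PRC1, PRC2, developmental transcription factors known as Polycomb targets, Hox, pluripotency, primed-state, retinoic acid response, neural, primitive streak and mesoderm and extraembryonic endoderm genes. The rest are trophectoderm, 2-cell-like, fibroblast, germline, p53 target, interferon response, cell cycle, cholesterol synthesis, Wnt target, immediate early and replication-dependent histone genes. A list needed at least 5 measured members. List medians are medians of edgeR log2 changes with members at 3 counts or fewer over a group set at that floor, and plain medians for interactions. Median, mean and test of a list differed in sign in 32 of the 207 tests and in 0 of the 65 called. Genes were named by a rule: the targets, the 4 largest rises and falls of each comparison, up to 4 members with the lowest p of each list with at least 3 calls, and 10 reference genes. The largest changes needed an adjusted p under 0.05, at least 5 CPM in a group and, outside interactions, groups that do not overlap, and left out gene models without a name, histone genes and pseudogenes. The reference genes include Pou5f1, Nanog, Sox2, Rarb, Cyp26a1, Hoxb1, Gata4, Gata6 and T, and some genes that the rule names are not reported here.

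Replicate numbers were checked for pairing by the correlation of residuals between libraries of the same number. Of the 7 pairs of groups compared directly, RA shCdk8 and RA shNMC had all 3 correlations over 0.1 (0.475, 0.287 and 0.537). Within the interactions they were also over 0.1 for RA shCdk8 and mESC shCdk8 (0.358, 0.169 and 0.371), a pair that defines RA-induced genes, for RA shNMC and mESC shCdk8 (0.356, 0.143 and 0.41) and for RA shNMC and mESC shMed12 (0.290, 0.158 and 0.373). The labels state no pairing, so libraries were treated as unpaired and a replicate block was run as an alternative. Other alternatives were median-ratio size factors, no low-count filter or a stricter one (1 CPM in 3 libraries), DESeq2 1.42.0, a fit on the compared groups alone, untransfected cells as control and leaving out each library in turn. Where leaving out a library leaves 2 in a group, the spread is still pooled over all groups. Leaving out the library labelled shRing1b replicate 3 was planned for the shRing1b comparison, as was the edgeR fit of shRing1b and shNMC libraries alone. Other fits without that library, the other shRing1b fits on the compared groups alone, the overlaps on the compared groups alone and limma voom with sample weights were added after the data were seen. Between TMM and median-ratio scaling the median of all genes moved by at most 0.0074 on the log2 scale. Known changes were added to simulated counts with the spread of these libraries. Of 200 changed genes in a pairwise comparison 41% were recovered at 1.5-fold and 75% at 2-fold, with 2.52% of calls false. For the interaction 15% and 65% were recovered, with 5.88% of calls false. A list raised by 0.5 on the log2 scale was called, and 0 of the other lists were, but shuffling the labels of the real libraries gave a median of 64 list calls, close to the 65 reported. A mouse RefSeq gene table for build GRCm38.p6 served for gene types alone, since it differs from mm9, and no coordinates are given. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.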

Results

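The hairpins target Med12 and Cdk8, which encode members of the Mediator kinase module, and Rnf2, which encodes the Polycomb protein Ring1b, in mouse embryonic stem cells (mESCs). The comparisons ask how each hairpin changes gene expression in pluripotent cells, and, for Med12 and Cdk8, after 24 h of retinoic acid (RA) without LIF. Med12 stood at 41.7 ± 5.8 CPM (mean ± SD, n = 3) with shMed12 in mESCs and 133 ± 5.5 CPM with the hairpin control shNMC. The log2 change was -1.68 (SE 0.16, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.0e-08). After RA it stood at 48.5 ± 11.5 CPM against 119 ± 24.9 CPM (log2 -1.30, SE 0.16, edgeR adjusted p = 1.5e-06). Cdk8 fell to 12.8 ± 2.3 CPM from 53.4 ± 3.1 CPM in mESCs with shCdk8 (log2 -2.06, SE 0.15, edgeR adjusted p = 8.8e-08). After RA it fell to 9.90 ± 2.2 CPM from 45.6 ± 2.7 CPM (log2 -2.20, SE 0.15, edgeR adjusted p = 2.5e-08). Each of the 3 shMed12 and 3 shCdk8 libraries of either state lay below all 3 shNMC libraries of that state for its own target. Rnf2 stood at 52.4, 64.2 and 207 CPM in the shRing1b libraries 1, 2 and 3, against 240.0 to 277 CPM with shNMC and 221 to 303 CPM in untransfected cells. The library labelled shRing1b replicate 3 goes against its label in this respect. The log2 change of Rnf2 was -1.27 with it (SE 0.29, edgeR adjusted p = 0.0039) and -2.16 without it. No hairpin moved another target past the threshold in mESCs. With shMed12 the log2 changes were 0.06 for Cdk8 and -0.26 for Rnf2, and with shCdk8 -0.20 for Med12 and -0.17 for Rnf2. With shRing1b they were -0.06 for Med12 and 0.10 for Cdk8.

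**Figure D1:**
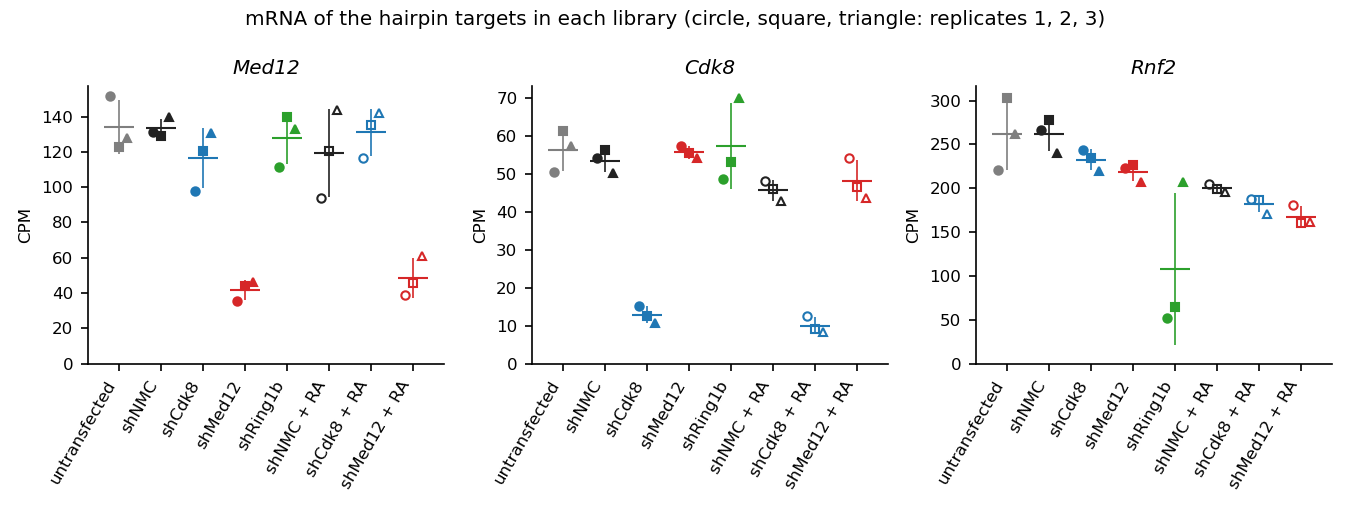
CPM of Med12, Cdk8 and Rnf2 in each library by group, with replicates 1, 2 and 3 as circle, square and triangle, mESCs filled and RA open, the group mean as a horizontal line and its SD as a vertical one. Med12 and Cdk8 are low in all 3 libraries of their own hairpin in both states, and Rnf2 is low in shRing1b libraries 1 and 2 but at 207 CPM in library 3.

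Libraries separated by RA and by shMed12 on both leading principal components, which held 46.9% and 23.9% of the variance. On the first, shMed12 mESCs scored -16.6 to -6.05, between the shNMC mESCs (58.3 to 67.3) and the RA shNMC libraries (-51.5 to -37.3), and shRing1b mESCs scored 19.5 to 45.4. The second set shMed12 apart from the other lines in both states. The labels do not say whether the 3 replicates of a group are separate cultures, so every p-value measures only the spread between these samples. The 6 untransfected and shRing1b libraries form a technical set of their own. In them reads with several alignments made 20.0% to 21.7% of all entries, against 44.1% to 49.1% in the other 18, so shRing1b and its shNMC control come from different sets.

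**Figure D2:**
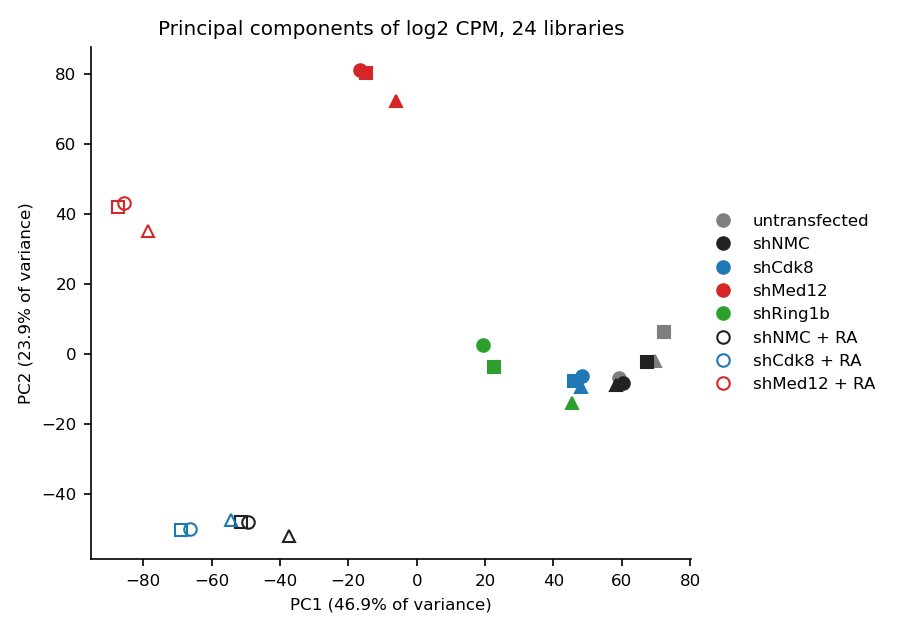
Scores of the 24 libraries on the 2 leading principal components of log2 CPM (46.9% and 23.9% of the variance), 1 point per library, coloured by hairpin, mESCs filled and RA open. RA and mESC libraries lie apart on the horizontal axis, with shMed12 mESCs nearest to the RA side among mESCs, and shMed12 libraries of both states lie apart from the rest on the vertical axis.

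In the shNMC cells 24 h of RA without LIF raised genes of the retinoid pathway and the Hox clusters and lowered pluripotency genes. No group had LIF withdrawn without RA. Effects of RA and of the loss of LIF thus cannot be told apart, here or in the interactions. Cyp26a1, which encodes the enzyme that degrades RA, rose from 1.43 ± 0.13 to 333 ± 64.5 CPM (log2 7.85, SE 0.32, edgeR adjusted p = 1.6e-13, n = 3). The receptor gene Rarb (4.56, SE 0.20) and the anterior Hox genes Hoxb1 (8.22, SE 0.40) and Hoxb2 (8.70, SE 0.55) rose with it (log2 changes in brackets). Hoxb5 had 1 read over the 3 mESC libraries and 1713 after RA, a ratio of 1442 with a 95% counting interval of 258.4 to 56974, which covers counting error and no other spread. Pou5f1 fell from 912 ± 27.8 to 442 ± 48.7 CPM (log2 -1.04, SE 0.12), and Nanog (-1.34, SE 0.17) and Sox2 (-0.77, SE 0.08) fell too. The largest falls were in Tdh (-4.97, SE 0.28), which encodes a threonine-degrading enzyme of naive cells, Foxd3 (-4.73, SE 0.38), Gna14 (-4.25, SE 0.29) and Tgm3 (-3.79, SE 0.29). T (1.62, SE 0.50) rose, while Gata4 (0.63) and Gata6 (1.02) did not pass.

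Among 38 measured Hox genes 35 rose, 1 fell and 2 did not pass, with a median log2 change of 3.29. The Hox list gave a camera adjusted p of 5.1e-12, and adjusted p = 0.36 with an estimated correlation. Of 28 retinoic acid response genes 22 rose, 2 fell and 4 did not pass, with Dhrs3 (4.46) near the top. The retinoic acid response list gave a camera adjusted p of 1.3e-11, and adjusted p = 0.065 with an estimated correlation. Of 30 pluripotency genes 1 rose, 25 fell and 4 did not pass, among them Zfp42 (-1.89), Klf4 (-1.98), Tdgf1 (-2.82) and Stat3 (-1.21). The pluripotency list gave a camera adjusted p of 5.1e-12, and adjusted p = 0.072 with an estimated correlation. Of 59 developmental transcription factors known as Polycomb targets 37 rose, 4 fell and 18 did not pass (41 and 4 adjusted over the list alone), with Irx3 (3.71) and Six2 (4.74) among the rises. The Polycomb-target list gave a camera adjusted p of 4.3e-05, and adjusted p = 0.65 with an estimated correlation. Of 11 PRC2 subunits 2 rose, 9 fell and 0 did not pass, Eed (-1.47), Suz12 (-0.63) and Ezh2 (-0.48) among the falls. The PRC2 list gave a camera adjusted p of 0.0076, and adjusted p = 0.31 with an estimated correlation. Of 27 cell cycle genes 0 rose, 14 fell and 13 did not pass, including Ccnd1 (-1.60) and Mcm7 (-0.66). The cell cycle list gave a camera adjusted p of 2.9e-04, and adjusted p = 0.36 with an estimated correlation. Germline genes such as Sohlh2 (1.46) and Brdt (1.84) leaned upward, with 12 rises and 2 falls of 20 (13 and 2 adjusted over the list alone). The germline list gave a camera adjusted p of 0.018, and adjusted p = 0.60 with an estimated correlation, and did not pass without replicate 2 of every group (adjusted p = 0.0574).

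Trophectoderm genes had 11 rises with RA, Gata2 (2.20) and Dlx3 (2.74) among them, and 1 fall of 15 (12 and 1 adjusted over the list alone). The trophectoderm list gave a camera adjusted p of 0.021, and adjusted p = 0.57 with an estimated correlation. Primitive streak and mesoderm genes had 10 rises, Foxc1 (2.88) and Wnt3 (1.96) among them, and 1 fall of 19 (11 and 1 adjusted over the list alone). The primitive streak list gave a camera adjusted p of 0.047, and adjusted p = 0.65 with an estimated correlation, and did not pass without replicate 1 or 2 of every group (adjusted p = 0.0637 and 0.0533), nor with median-ratio size factors (adjusted p = 0.0508). Immediate early genes split, 6 up with Jun (2.79) and 9 down with Myc (-2.63) (limma camera adjusted p = 0.40). In all, 4438 genes rose and 3925 fell with RA of 16280 tested, 2660 and 619 of them by at least 2-fold (edgeR quasi-likelihood, two-sided, Benjamini-Hochberg adjusted p under 0.05).

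**Figure D3:**
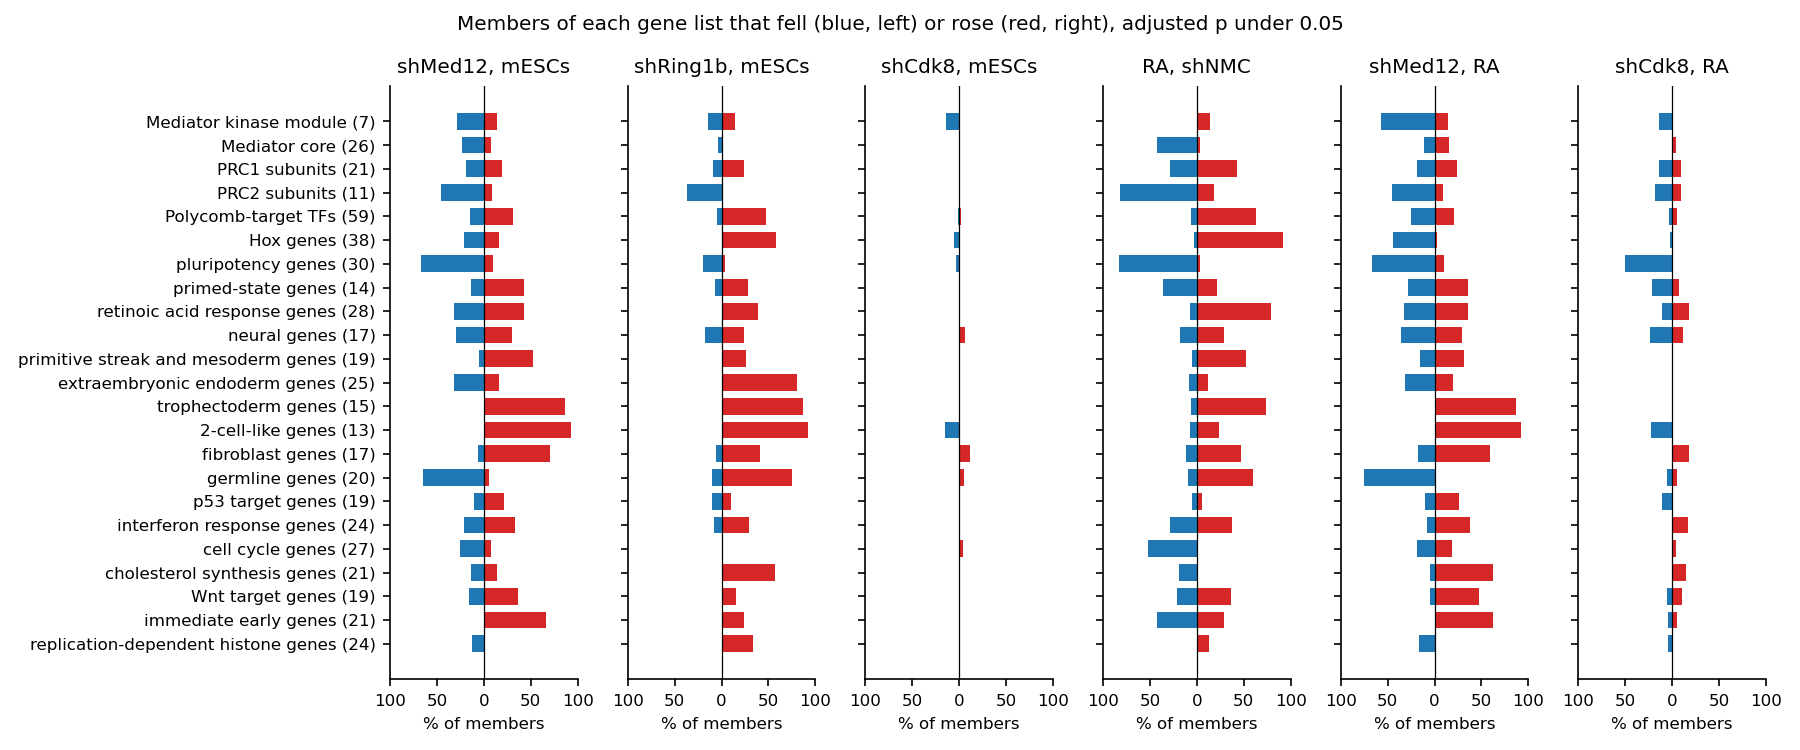
Percent of the measured members of each gene list that rose or fell (horizontal axis) in each of 6 comparisons, 1 bar per direction and list. With RA 35 of 38 Hox genes rose, and with shMed12 in mESCs 13 of 15 trophectoderm genes rose and 20 of 30 pluripotency genes fell.

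With the Med12 hairpin, mESCs kept in LIF had more transcripts of trophectoderm and fibroblast genes and fewer of pluripotency genes. The keratin gene Krt18 rose from 11.2 ± 1.9 to 388 ± 52.1 CPM (log2 5.11, SE 0.29, edgeR adjusted p = 1.7e-11, n = 3). The smooth-muscle gene Tagln rose from 2.10 ± 0.44 to 273 ± 26.9 CPM (log2 7.02, SE 0.44, edgeR adjusted p = 7.1e-11). The actin gene Acta2 rose from 0.239 ± 0.072 to 59.0 ± 9.8 CPM (log2 7.94, SE 0.62), and the interferon-induced GTPase gene Gbp1 from 0.245 ± 0.10 to 53.1 ± 19.3 CPM (log2 7.72, SE 0.46). Col3a1 and Cav1 had 1 and 3 reads over the 3 shNMC libraries, so their rises are ratios with 95% counting intervals, which cover counting error and no other spread. The ratio was 915 (163.7 to 36167) for Col3a1 and 533 (182 to 2587) for Cav1. Sox2 fell from 805 ± 34.5 to 439 ± 13.6 CPM (log2 -0.88, SE 0.08, edgeR adjusted p = 6.5e-09). Nanog fell from 62.4 ± 4.3 to 32.5 ± 3.6 CPM (log2 -0.94, SE 0.17) and Pou5f1 from 912 ± 27.8 to 639 ± 70.9 CPM (log2 -0.51, SE 0.12). The largest falls were in the metal transporter gene Slc11a1 (-5.34, SE 0.44), the proteoglycan gene Srgn (-5.23, SE 0.77), the endocytic receptor gene Cubn (-4.70, SE 0.80) and Inhbb (-4.67, SE 0.32), which encodes an activin subunit.

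Of 15 trophectoderm genes 13 rose, 0 fell and 2 did not pass, with a median log2 change of 4.34, among them Hand1 (6.05, SE 0.30), Krt7 (5.16, SE 0.38) and Krt19 (4.35, SE 0.28). The trophectoderm list gave a camera adjusted p of 3.0e-09, and adjusted p = 0.065 with an estimated correlation. In shNMC mESCs 7 of these 15 genes reached 1 CPM, and 4 of the 15 are also on another list. Of 17 fibroblast genes 12 rose, 1 fell and 4 did not pass (13 and 2 adjusted over the list alone), with Col1a1 (3.33) and Col6a1 (3.55) beside Tagln. The fibroblast list gave a camera adjusted p of 1.6e-06, and adjusted p = 0.065 with an estimated correlation. Of these 17 genes 9 reached 1 CPM with shNMC and 0 are on another list. Of 30 pluripotency genes 3 rose, 20 fell and 7 did not pass, led by Tet2 (-1.86, SE 0.10), Klf4 (-1.84, SE 0.13), Prdm14 (-2.39, SE 0.17) and Stat3 (-0.99, SE 0.08). The pluripotency list gave a camera adjusted p of 1.7e-07, and adjusted p = 0.20 with an estimated correlation. Primed-state genes moved both ways, 6 up with Cldn6 (3.01), Pou3f1 (1.91) and Dnmt3b (1.36) and 2 down with Zic2 (-1.46) of 14 (8 and 2 adjusted over the list alone). The primed-state list gave a camera adjusted p of 0.039, and adjusted p = 0.60 with an estimated correlation, and did not pass without replicate 1 of every group (adjusted p = 0.0525). Primitive streak and mesoderm genes had 10 rises and 1 fall of 19 (10 and 2 adjusted over the list alone). The primitive streak list gave a camera adjusted p of 0.021, and adjusted p = 0.60 with an estimated correlation, and did not pass without replicate 1 of every group (adjusted p = 0.0525). Of these, T went from 0.375 ± 0.042 to 12.9 ± 8.3 CPM (log2 5.10, SE 0.50), and Wnt3 (4.44, SE 0.36) and Eomes (2.20, SE 0.25) also rose. Immediate early genes had 14 rises and 0 falls of 21 (15 and 0 adjusted over the list alone), including Klf6 (1.59), Dusp6 (1.16) and Dusp1 (1.41). The immediate early list gave a camera adjusted p of 8.1e-06, and adjusted p = 0.23 with an estimated correlation. Germline genes had 13 falls and 1 rise of 20, among them Hormad1 (-2.59), Smc1b (-2.63) and Sohlh2 (-1.43). The germline list gave a camera adjusted p of 4.8e-04, and adjusted p = 0.36 with an estimated correlation. Genes of the 2-cell-like state had 12 rises and 0 falls of 13, for instance Tdpoz3 (2.84) and Dub1 (1.90). The 2-cell-like list gave a camera adjusted p of 0.0027, and adjusted p = 0.68 with an estimated correlation.

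Other lists did not pass camera with shMed12 in mESCs, and most of them held members that moved either way. Retinoic acid response genes had 12 rises and 9 falls of 28 (limma camera adjusted p = 0.82), with Stra8 (-3.24) and Crabp1 (-1.66) down. Before any RA Rarb (-2.09, SE 0.24) was lower and Cyp26a1 (1.54, SE 0.31) was higher, while Hoxb1 (0.24) did not pass. The endoderm genes Gata6 (-1.85, SE 0.51) and Hnf4a (-3.19) fell and Gata4 (-0.98) did not pass. Their list had 4 rises and 8 falls of 25 (limma camera adjusted p = 0.35). Neural genes had 5 rises, with Nes (2.90), and 5 falls, with Sox1 (-3.25) and Ncam1 (-2.23), of 17 (limma camera adjusted p = 0.76). Interferon response genes had 8 rises, with Oasl2 (4.98), and 5 falls of 24 (limma camera adjusted p = 0.27). Wnt target genes had 7 rises, with Axin2 (1.17), and 3 falls of 19 (limma camera adjusted p = 0.18, and 0.0292 without replicate 3 of every group). Within Mediator, the paralogue Med12l rose from 7.66 ± 1.7 to 35.5 ± 3.4 CPM (log2 2.22, SE 0.22) and Cdk19 (-0.51) fell. The PRC1 genes Pcgf5 (1.41) and Phc2 (1.07) rose and Phc1 (-0.84) fell, and the PRC2 gene Ezh2 (-0.44) fell. Counts of rises and falls were 2 and 6 of 26 Mediator core genes, 4 and 4 of 21 PRC1 subunits and 1 and 5 of 11 PRC2 subunits (limma camera adjusted p = 0.89, 0.89 and 0.22). They were 1 and 2 of 7 kinase module genes, 6 and 8 of 38 Hox genes and 18 and 9 of 59 Polycomb-target factors (limma camera adjusted p = 0.50, 0.89 and 0.46). For p53 targets they were 4 and 2 of 19 and for cell cycle genes 2 and 7 of 27 (limma camera adjusted p = 0.41 and 0.22). For cholesterol synthesis they were 3 and 3 of 21 and for replication-dependent histone genes 0 and 3 of 24 (limma camera adjusted p = 0.81 and 0.27). Over all 16280 genes tested 3352 rose and 3242 fell with shMed12 in mESCs, 1700 and 965 by at least 2-fold (edgeR quasi-likelihood, two-sided).

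**Figure D4:**
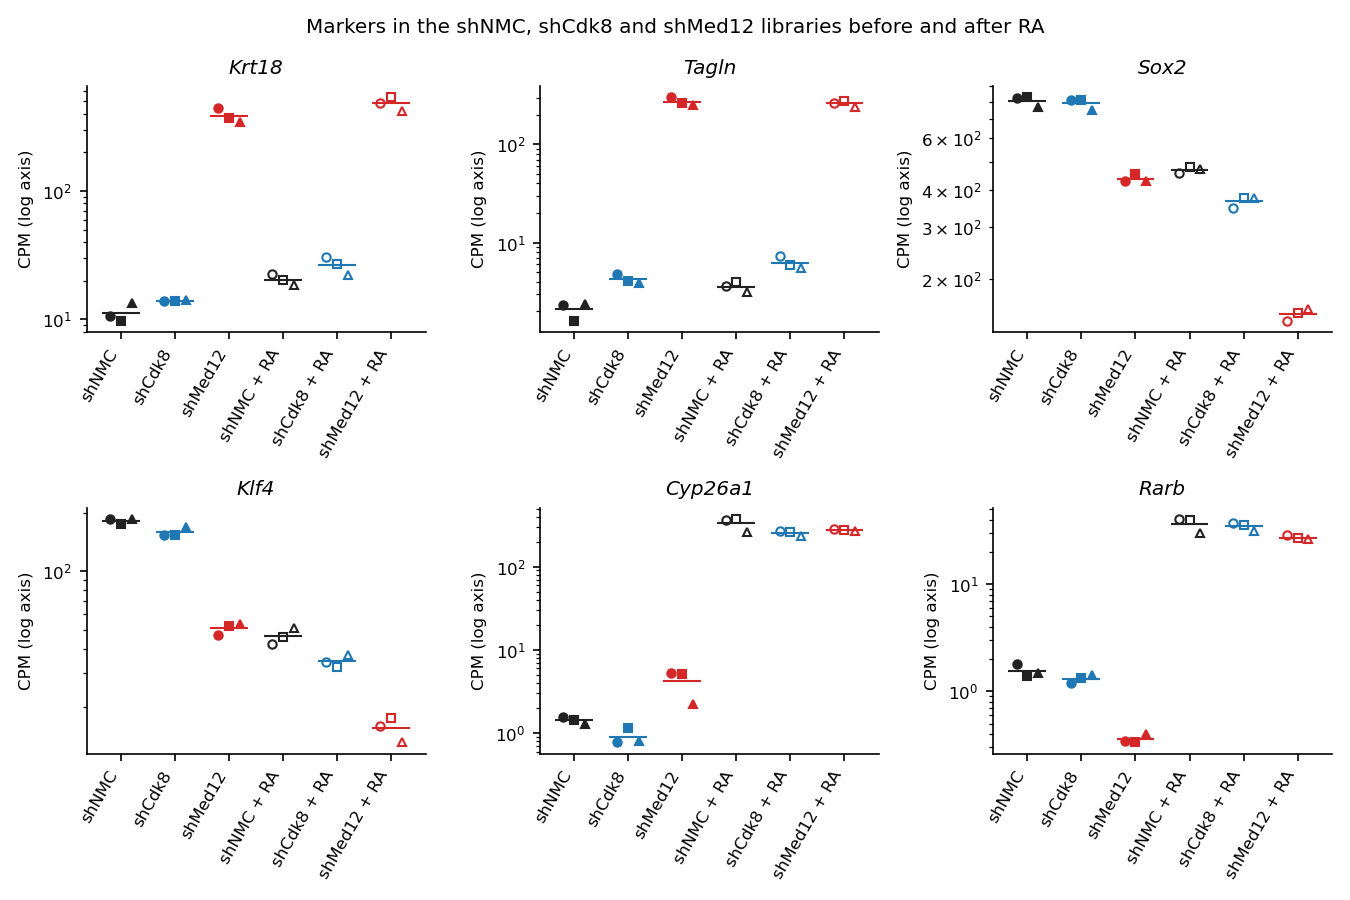
CPM (log axis) of marker genes in each library by group, mESCs filled and RA open, replicates as circle, square and triangle, with the group mean as a line. Krt18 and Tagln are high in shMed12 libraries of both states, and Cyp26a1 rises with RA in every line shown.

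After RA, trophectoderm and fibroblast genes were again higher and pluripotency genes lower with shMed12 than with shNMC. Sox2 stood at 152 ± 7.3 CPM against 471 ± 10.9 CPM (log2 -1.63, SE 0.08, edgeR adjusted p = 2.8e-12, n = 3), with Pou5f1 (-0.70) and Nanog (-0.74) also lower. The RA targets Cyp26a1 (-0.28) and Hoxb1 (-0.04) did not pass, nor did Gata4 (-0.34). Acta2 (8.07, SE 0.64), Tagln (6.21, SE 0.42) and the troponin gene Tnnt3 (6.75, SE 0.40) rose most. Col3a1 had 1 read over the 3 shNMC libraries and a ratio of 1196 (95% counting interval 214.2 to 47263). Cubn (-4.99, SE 0.78), Srgn (-4.89, SE 0.70), Trim66 (-3.94, SE 0.53) and Slc11a1 (-3.84, SE 0.41) fell most. Gata6 (-1.49) fell, a call that ended without shMed12 replicate 3 (edgeR adjusted p = 0.056). T (1.27) rose, a call that ended without shMed12 replicate 1 or 2 or shNMC replicate 1, 2 or 3 (edgeR adjusted p = 0.052 to 0.090). Rarb (-0.43) fell, a call that ended without shMed12 replicate 1, 2 or 3 or shNMC replicate 1 or 2 (edgeR adjusted p = 0.054 to 0.15).

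After RA with shMed12, 1 of 38 Hox genes rose, 17 fell and 20 did not pass (2 and 17 adjusted over the list alone). Among the falls were Hoxb13 (-1.97, SE 0.33), Hoxb9 (-1.17, SE 0.22), Hoxb4 (-1.30, SE 0.25) and Hoxa4 (-1.11, SE 0.22). The Hox list gave a camera adjusted p of 0.0027, and adjusted p = 0.81 with an estimated correlation. Of 30 pluripotency genes 3 rose, 20 fell and 7 did not pass, Tcl1 (-2.69) and Fgf4 (-1.65) among the falls. The pluripotency list gave a camera adjusted p of 1.3e-05, and adjusted p = 0.31 with an estimated correlation. Of 20 germline genes 0 rose, 15 fell and 5 did not pass (0 and 16 adjusted over the list alone), with Dazl (-2.12) and Hormad1 (-2.28). The germline list gave a camera adjusted p of 3.7e-07, and adjusted p = 0.17 with an estimated correlation. Of 15 trophectoderm genes 13 rose, 0 fell and 2 did not pass, with Krt18 (4.57), Krt7 (3.96) and Hand1 (4.01). The trophectoderm list gave a camera adjusted p of 1.1e-08, and adjusted p = 0.066 with an estimated correlation. Of 17 fibroblast genes 10 rose, 3 fell and 4 did not pass (10 and 4 adjusted over the list alone), with Col1a1 (1.93) beside Tagln. The fibroblast list gave a camera adjusted p of 0.0023, and adjusted p = 0.23 with an estimated correlation. Of 13 genes of the 2-cell-like state 12 rose, 0 fell and 1 did not pass, with Zfp352 (1.59). The 2-cell-like list gave a camera adjusted p of 0.0032, and adjusted p = 0.70 with an estimated correlation. Of 21 immediate early genes 13 rose, 0 fell and 8 did not pass, with Junb (2.36) and Dusp6 (1.05). The immediate early list gave a camera adjusted p of 5.4e-05, and adjusted p = 0.29 with an estimated correlation. Of 19 Wnt target genes 9 rose, 1 fell and 9 did not pass (12 and 2 adjusted over the list alone), with Sp5 (5.30), Cdx2 (4.27) and Axin2 (1.31). The Wnt target list gave a camera adjusted p of 0.018, and adjusted p = 0.57 with an estimated correlation. Of 21 cholesterol synthesis genes 13 rose, 1 fell and 7 did not pass (14 and 1 adjusted over the list alone), with Sqle (0.73) among the rises. The cholesterol synthesis list gave a camera adjusted p of 0.0045, and adjusted p = 0.77 with an estimated correlation. Interferon response genes had 9 rises, with Ddx58 (2.23) and Cxcl10 (3.66), and 2 falls of 24 (limma camera adjusted p = 0.052). This list passed as higher with the replicate number as a block (limma camera adjusted p = 0.0434) and without replicate 1 or 3 of every group (0.0467 and 0.0317). Across the genome 3463 genes rose and 3351 fell with shMed12 after RA, 1218 and 1265 by at least 2-fold (edgeR quasi-likelihood, two-sided).

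The RA response itself differed with shMed12 for 820 genes by edgeR's interaction term, 283 with a more positive and 537 with a more negative response than in shNMC cells. Gabrp, which encodes a GABA receptor subunit, had the most positive difference in log2 change (7.65, SE 0.45, edgeR adjusted p = 7.3e-10). Gna14 (3.07, SE 0.39), Fgf17 (2.78, SE 0.50) and Pou2f3 (2.41, SE 0.40) came next. The most negative were Cav1 (-5.03, SE 0.57), T (-3.83, SE 0.64), Ms4a4d (-3.61, SE 0.44) and Otx2 (-3.52, SE 0.53). Sox2 fell further with RA in shMed12 than in shNMC cells (-0.75, SE 0.11, edgeR adjusted p = 1.9e-04). Cyp26a1 rose by less (-1.82, SE 0.38) from a higher level before RA, and Rarb by more (1.66, SE 0.30) from a lower one. Pou5f1 (-0.19), Nanog (0.20), Hoxb1 (-0.28), Gata4 (0.64) and Gata6 (0.36) did not pass. Hand1 (-2.04), Eomes (-1.76) and Wnt3 (-2.03) were more negative and Ddx58 (1.96), Stra8 (1.52) and Sox1 (2.13) more positive. Fibroblast genes had 0 more positive and 5 more negative responses of 17, with Col6a1 (-2.61) and Col1a1 (-1.40). The fibroblast list gave a camera adjusted p of 8.0e-04, and adjusted p = 0.20 with an estimated correlation. Primed-state genes had 0 more positive and 4 more negative of 14 (0 and 8 adjusted over the list alone). The primed-state list gave a camera adjusted p of 0.0065, and adjusted p = 0.38 with an estimated correlation, and did not pass without replicate 1 of every group (adjusted p = 0.0596). Trophectoderm genes had 0 more positive and 2 more negative of 15 (1 and 5 adjusted over the list alone). The trophectoderm list gave a camera adjusted p of 0.0026, and adjusted p = 0.36 with an estimated correlation. Hox genes had 0 more positive and 3 more negative of 38. The Hox list gave a camera adjusted p of 0.035, and adjusted p = 0.90 with an estimated correlation, and did not pass without replicate 1 or 2 of every group (adjusted p = 0.0949 and 0.096). For cholesterol synthesis genes 0 of 21 passed by edgeR and 0 by DESeq2, with 7 more positive at an unadjusted edgeR p under 0.05 and a median of 0.42. The cholesterol synthesis list gave a camera adjusted p of 1.8e-04, and adjusted p = 0.65 with an estimated correlation. For cell cycle genes 1 of 27 passed, as more positive. The cell cycle list gave a camera adjusted p of 0.017, and adjusted p = 0.60 with an estimated correlation, and did not pass without replicate 2 of every group (adjusted p = 0.0882).

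The count of 820 genes was 1250 by DESeq2 and 2237 from the compared groups alone, and it moved by more than 1.5 times when single libraries were left out. It was 528 without RA shMed12 replicate 2, 505 and 517 without RA shNMC replicate 1 and 2, and 489 and 522 without mESC shMed12 replicate 1 and 2. It was 1471 without the library labelled shRing1b replicate 3, which enters only through the shared spread. RA induced 2602 genes in the shCdk8 line by a log2 change of at least 1 (edgeR adjusted p under 0.05). Their definition shares no library with the test that follows, but residuals of RA shCdk8 and RA shNMC correlated by replicate number (0.475, 0.287 and 0.537). Their median interaction with shMed12 was -0.58 (log2), with 82.8% negative against 49.7% of all genes. The limma camera test gave p = 1.9e-24, and p = 5.8e-04 with an estimated correlation, and fry gave p = 9.7e-05. Before RA they lay higher with shMed12 than with shNMC (median 0.57) and after RA close to it (median -0.08), so their median log2 change with RA was 1.08 against 1.73 with shNMC. By single genes 16 of them passed with a more positive and 351 with a more negative response. For 1565 genes induced in the shMed12 line, the median interaction with shCdk8 was -0.00 (limma camera p = 0.20, and p = 0.57 with an estimated correlation, fry p = 0.81).

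The Cdk8 hairpin changed fewer genes in mESCs than the Med12 hairpin, and Pou5f1 (-0.17), Nanog (0.00) and Sox2 (-0.03) did not pass. The sodium pump gene Atp1a4 rose from 0.537 ± 0.016 to 7.61 ± 0.21 CPM (log2 3.82, SE 0.34, edgeR adjusted p = 1.1e-06, n = 3). The homeobox gene Emx2 rose from 0.610 ± 0.10 to 5.41 ± 0.38 CPM (log2 3.14, SE 0.41) and Sh3bgrl from 19.6 ± 1.0 to 54.6 ± 4.3 CPM (log2 1.48, SE 0.13). The growth factor carrier gene Fgfbp1 (2.26, SE 0.45) rose, a call that ended without shNMC replicate 1 (edgeR adjusted p = 0.053). Txnip (-1.49, SE 0.39) fell, a call that ended without shCdk8 replicate 1, 2 or 3 or shNMC replicate 1 or 3 (edgeR adjusted p = 0.060 to 0.18). Zscan4a, a gene of the 2-cell-like state, fell to 4.32 ± 0.94 from 12.2 ± 2.5 CPM. Its call ended without any 1 of the 3 shCdk8 or 3 shNMC libraries (edgeR adjusted p = 0.086 to 0.18). Of 13 genes of that state 0 rose, 2 fell and 11 did not pass (0 and 8 adjusted over the list alone), with a median log2 change of -1.21. The 2-cell-like list gave a camera adjusted p of 8.6e-04, and adjusted p = 0.66 with an estimated correlation. Rarb (-0.24), Cyp26a1 (-0.66), Hoxb1 (-0.47), Gata4 (0.29), Gata6 (1.07) and T (0.62) did not pass. Of 17 fibroblast genes 2 rose and 0 fell (3 and 0 adjusted over the list alone). The fibroblast list gave a camera adjusted p of 0.039, and adjusted p = 0.43 with an estimated correlation, and did not pass without replicate 2 of every group (adjusted p = 0.166). Of 38 Hox genes 0 rose and 2 fell. The Hox list gave a camera adjusted p of 0.023, and adjusted p = 0.89 with an estimated correlation, and did not pass without replicate 3 of every group (adjusted p = 0.0512). Of 11 PRC2 subunits 0 passed by edgeR and 1 by DESeq2, with 5 lower at an unadjusted edgeR p under 0.05 and a median of -0.13. The PRC2 list gave a camera adjusted p of 0.012, and adjusted p = 0.36 with an estimated correlation, and did not pass without replicate 2 of every group (adjusted p = 0.0587). Of 25 extraembryonic endoderm genes 0 passed by edgeR and 0 by DESeq2, with 3 higher at an unadjusted edgeR p under 0.05 and a median of 0.52. The extraembryonic endoderm list gave a camera adjusted p of 0.043, and adjusted p = 0.90 with an estimated correlation, and did not pass without replicate 1 of every group (adjusted p = 0.0949). In total 365 genes rose and 231 fell with shCdk8 in mESCs, 111 and 40 by at least 2-fold (edgeR quasi-likelihood, two-sided). The sum of 596 was 905 with the replicate number as a block, 992 with untransfected cells as control, 1151 by DESeq2 and 2334 from the compared groups alone. It was 242, 170 and 282 without shCdk8 replicate 1, 2 and 3, and 198, 245 and 240 without shNMC replicate 1, 2 and 3. Without the library labelled shRing1b replicate 3 the sum was 1350.

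After RA 15 of 30 pluripotency genes were lower with shCdk8 than with shNMC. Klf2 stood at 47.0 ± 5.0 CPM against 119.9 ± 17.5 CPM (log2 -1.35, SE 0.14, edgeR adjusted p = 4.7e-06, n = 3). Fgf4 stood at 62.0 ± 15.9 against 160.0 ± 26.1 CPM (log2 -1.37, SE 0.15) and Zfp42 at 83.3 ± 13.8 against 155 ± 9.7 CPM (log2 -0.90, SE 0.12). Sox2 (-0.36, SE 0.08) and Fbxo15 (-0.94, SE 0.17) fell too. Nanog (-0.71) fell, a call that ended without shCdk8 replicate 1 or 2 or shNMC replicate 3 (edgeR adjusted p = 0.057 to 0.093). Pou5f1 (-0.39) fell, a call that ended without shCdk8 replicate 1 or 2 or shNMC replicate 1, 2 or 3 (edgeR adjusted p = 0.058 to 0.24). Of 30 pluripotency genes 0 rose, 15 fell and 15 did not pass (1 and 18 adjusted over the list alone), with a median log2 change of -0.38. The pluripotency list gave a camera adjusted p of 1.9e-07, and adjusted p = 0.20 with an estimated correlation. Trh, which encodes thyrotropin-releasing hormone, rose from 53.4 ± 11.8 to 268 ± 31.8 CPM (log2 2.33, SE 0.28), with Cyp1b1 (2.45, SE 0.34) and the GTPase genes Gbp2 (2.35, SE 0.35) and Irgm1 (2.24, SE 0.43). Pdha2 (-1.72, SE 0.28) and Chchd10 (-1.62, SE 0.19) fell most after Cdk8 itself. Ddit3 (-1.63, SE 0.43) fell, a call that ended without shCdk8 replicate 1 or 2 or shNMC replicate 3 (edgeR adjusted p = 0.094 to 0.13).

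With shCdk8 after RA, the RA targets Rarb (-0.08), Cyp26a1 (-0.38) and Hoxb1 (0.43) did not pass, nor did Gata4 (0.13), Gata6 (0.82) and T (0.25). Of 28 retinoic acid response genes 5 rose, 3 fell and 20 did not pass (7 and 4 adjusted over the list alone), with Dhrs3 (0.81) up. The retinoic acid response list gave a camera adjusted p of 0.025, and adjusted p = 0.60 with an estimated correlation. Of 24 interferon response genes 4 rose, 0 fell and 20 did not pass (9 and 1 adjusted over the list alone), with Oasl2 (1.58). The interferon response list gave a camera adjusted p of 0.0010, and adjusted p = 0.36 with an estimated correlation. Ddx58 stood at 24.8 ± 0.76 CPM against 8.73 ± 0.18 CPM. Genes of the 2-cell-like state had 0 rises and 3 falls of 13 (0 and 9 adjusted over the list alone). The 2-cell-like list gave a camera adjusted p of 0.0012, and adjusted p = 0.67 with an estimated correlation. Cholesterol synthesis genes had 3 rises and 0 falls of 21 (4 and 0 adjusted over the list alone). The cholesterol synthesis list gave a camera adjusted p of 0.0013, and adjusted p = 0.68 with an estimated correlation. PRC2 subunits had 1 rise and 2 falls of 11 (1 and 5 adjusted over the list alone), with Aebp2 (-0.55) down. The PRC2 list gave a camera adjusted p of 0.038, and adjusted p = 0.43 with an estimated correlation, and did not pass without replicate 2 of every group (adjusted p = 0.0848). Cell cycle genes had 1 rise and 0 falls of 27 (0 and 0 adjusted over the list alone), and as a list they were lower, with a median log2 change of -0.13. The cell cycle list gave a camera adjusted p of 0.018, and adjusted p = 0.60 with an estimated correlation. The PRC1 gene Phc1 (-0.94, SE 0.16) fell, the neural cadherin gene Cdh2 (1.27) and the homeobox gene Gbx2 (1.35) rose and Zic2 (-0.94) fell. Altogether 667 genes rose and 592 fell, 193 and 108 by at least 2-fold (edgeR quasi-likelihood, two-sided). The sum of 1259 was 2744 from the compared groups alone. It was 703 and 482 without shCdk8 replicate 1 and 2, 644 and 693 without shNMC replicate 1 and 2, and 2264 without the library labelled shRing1b replicate 3.

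The test of whether the RA response differs with shCdk8 passed 6 genes. With the replicate number as a block it passed 11, by DESeq2 27 and from the compared groups alone 38. Klf2 fell further with RA in shCdk8 than in shNMC cells (-1.32, SE 0.20, edgeR adjusted p = 0.0058). Ddx58 (1.13, SE 0.17, edgeR adjusted p = 0.0058) and Sulf1 (1.09, SE 0.14, edgeR adjusted p = 0.0016) had a more positive response. These 3 genes kept their calls with each library left out in turn. Ptpn13 (0.79, SE 0.14) lost its call without any 1 of the 12 libraries of the 4 groups (edgeR adjusted p = 0.068 to 0.20). Pcdh1 (1.36, SE 0.24) lost it without any of them but mESC shCdk8 replicate 3 and mESC shNMC replicate 2 (edgeR adjusted p = 0.052 to 0.18). Il17rd (0.68, SE 0.12, edgeR adjusted p = 0.041) is the sixth, named after its values were seen. The count was 3 without RA shCdk8 replicate 1 or 2, RA shNMC replicate 1 or 2, mESC shCdk8 replicate 1 or 2 or mESC shNMC replicate 1, and 16 without the library labelled shRing1b replicate 3. Pou5f1 (-0.23), Nanog (-0.71), Sox2 (-0.33), Rarb (0.16) and Cyp26a1 (0.28) did not pass. Nor did Hoxb1 (0.90), Gata4 (-0.16), Gata6 (-0.25) and T (-0.38). A larger loss after RA than before is thus shown for Klf2 and not for the core pluripotency factors. Pluripotency genes as a list had a more negative response, with 1 of 30 past the threshold (0 and 8 adjusted over the list alone) and a median of -0.24. The pluripotency list gave a camera adjusted p of 1.1e-08, and adjusted p = 0.17 with an estimated correlation. For 3 further lists camera alone gave a more positive response: of interferon response, retinoic acid response and cholesterol synthesis genes 1 of 24, 0 of 28 and 0 of 21 passed by edgeR. Of the last pair of lists 0 members passed by DESeq2, and 2 and 0 had an unadjusted edgeR p under 0.05. The interferon response list gave a camera adjusted p of 0.0046, and adjusted p = 0.43 with an estimated correlation, and did not pass without replicate 2 or 3 of every group (adjusted p = 0.0588 and 0.0541). The retinoic acid response list gave a camera adjusted p of 0.031, and adjusted p = 0.60 with an estimated correlation. The cholesterol synthesis list gave a camera adjusted p of 2.5e-04, and adjusted p = 0.65 with an estimated correlation.

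With the Ring1b hairpin, single germline, 2-cell-like, Hox and endoderm genes were higher than with shNMC in mESCs, while their lists passed camera only with the preset correlation and the endoderm list only with replicate 2. The germ-cell gene Dazl stood at 179, 175 and 71.1 CPM in libraries 1, 2 and 3, against 30.6 to 38.1 CPM with shNMC and 29.7 to 41.6 CPM in untransfected cells. Its log2 change against shNMC was 2.09 (SE 0.25, edgeR adjusted p = 1.2e-05). The 2-cell-like gene Tcstv3 stood at 170.5, 113 and 48.6 CPM against 20.5 to 27.7 with shNMC and 26.4 to 29.8 untransfected (log2 2.24, SE 0.34). The Polycomb target Hoxd1 stood at 3.10, 2.72 and 2.35 CPM against 0.806 to 1.2 and 0.639 to 1.26 (log2 1.34, SE 0.25). Endoderm genes were uneven: Gata6 stood at 10.5, 56.9 and 7.66 CPM against 3.88 to 4.96 with shNMC and 5.50 to 9.75 untransfected (log2 2.55, SE 0.47). Col4a1 stood at 389, 1423 and 111 CPM against 85.3 to 105 and 110.2 to 214 (log2 2.74, SE 0.49). Gata4 (1.96, SE 0.55) rose, a call that ended without shNMC replicate 2 (edgeR adjusted p = 0.059) or shRing1b replicate 2 (log2 0.54, edgeR adjusted p = 0.40). The largest rises named were in Tex13 (5.73, SE 0.94), Pramel6 (5.56, SE 0.97), Pramel7 (4.09, SE 0.55) and Dub1a (3.51, SE 0.49), and the largest falls in Slc11a1 (-1.76, SE 0.36), Nexn (-1.58, SE 0.22), Hhip (-1.39, SE 0.37) and Napsa (-1.38, SE 0.24). Sox2 (-0.44, SE 0.08) fell, while Pou5f1 (-0.08), Nanog (-0.11), Rarb (-0.34), Hoxb1 (1.10) and T (0.48) did not pass. Cyp26a1 (0.72) did not pass, but did without shRing1b library 3 (log2 1.08, edgeR adjusted p = 0.014). Other group values include this library, which goes against its label.

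**Figure D5:**
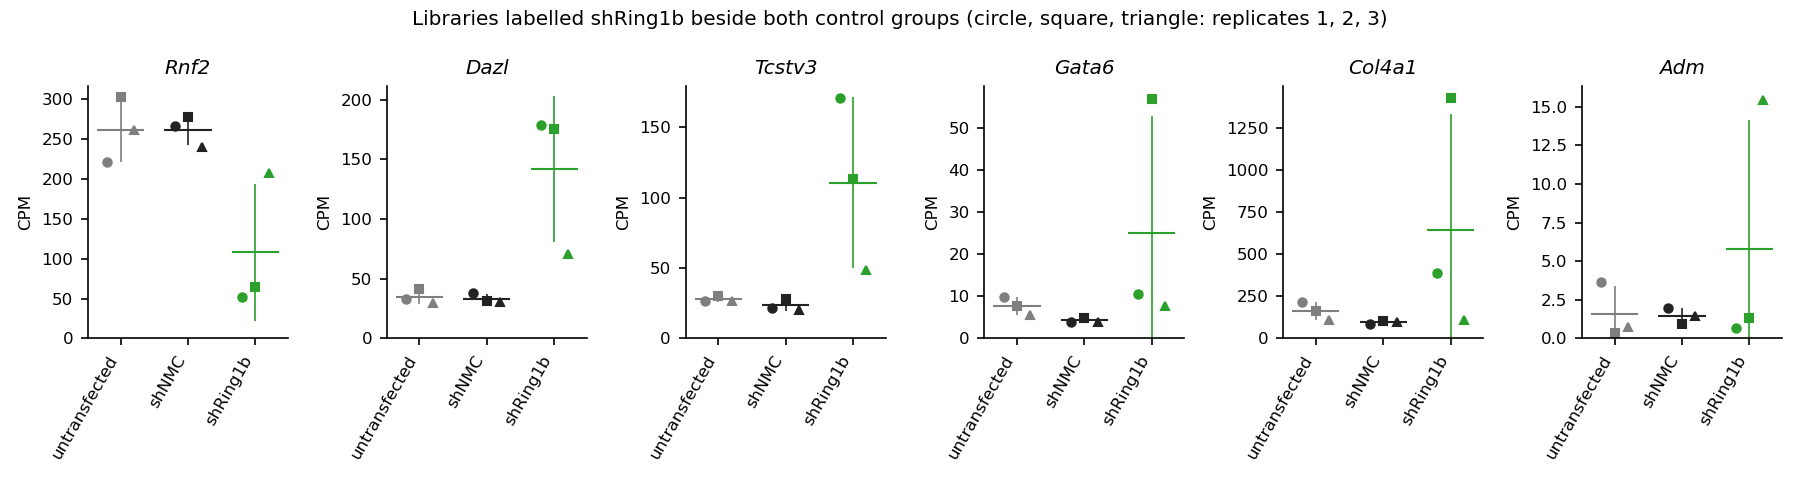
CPM of Rnf2 and genes of several classes in each untransfected, shNMC and shRing1b mESC library, replicates 1, 2 and 3 as circle, square and triangle, with the group mean as a horizontal line and its SD as a vertical one. Rnf2 is at 207 CPM in library 3 of shRing1b, and Gata6 at 56.9 CPM in library 2.

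Of 20 germline genes 15 rose, 2 fell and 3 did not pass with shRing1b (16 and 2 adjusted over the list alone), among them Sohlh2 (1.47), Mael (1.14) and Stk31 (0.95). The germline list gave a camera adjusted p of 1.7e-07, and adjusted p = 0.17 with an estimated correlation. Of 13 genes of the 2-cell-like state 12 rose, 0 fell and 1 did not pass, for instance Zfp352 (2.51) and Tcstv1 (2.33). The 2-cell-like list gave a camera adjusted p of 2.2e-08, and adjusted p = 0.36 with an estimated correlation. Of 38 Hox genes 22 rose, 0 fell and 16 did not pass (26 and 0 adjusted over the list alone), with Hoxb13 (1.89) and Hoxa9 (3.86). The Hox list gave a camera adjusted p of 4.0e-06, and adjusted p = 0.65 with an estimated correlation. Of 59 Polycomb-target transcription factors 28 rose, 3 fell and 28 did not pass (37 and 3 adjusted over the list alone), with Pax3 (3.47), Pax9 (3.26) and Hand1 (2.42). The Polycomb-target list gave a camera adjusted p of 2.5e-05, and adjusted p = 0.65 with an estimated correlation. Of 25 extraembryonic endoderm genes 20 rose, 0 fell and 5 did not pass, Sparc (1.67) and Cited1 (2.17) among them. The extraembryonic endoderm list gave a camera adjusted p of 4.3e-04, and adjusted p = 0.75 with an estimated correlation, and did not pass without replicate 2 of every group (adjusted p = 0.164). Library 2 stands apart in this list: Dab2 stood at 47.1, 331 and 15.3 CPM in libraries 1, 2 and 3 against 20.5 to 31.2 CPM with shNMC. Cubn stood at 83.4, 613 and 21.9 CPM against 35.9 to 47.4 CPM. Of 15 trophectoderm genes 13 rose, 0 fell and 2 did not pass (14 and 0 adjusted over the list alone), with Krt19 (2.73) and Krt8 (2.44). The trophectoderm list gave a camera adjusted p of 1.2e-07, and adjusted p = 0.080 with an estimated correlation. Of 21 cholesterol synthesis genes 12 rose, 0 fell and 9 did not pass (13 and 0 adjusted over the list alone), with Fdps (0.65) among the rises. The cholesterol synthesis list gave a camera adjusted p of 1.3e-04, and adjusted p = 0.65 with an estimated correlation, and did not pass without replicate 3 of every group (adjusted p = 0.117).

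Retinoic acid response genes had 11 rises and 0 falls of 28 with shRing1b (15 and 0 adjusted over the list alone), Crabp1 (0.91) among them. The retinoic acid response list gave a camera adjusted p of 0.0029, and adjusted p = 0.38 with an estimated correlation. Fibroblast genes had 7 rises and 1 fall of 17 (10 and 1 adjusted over the list alone), with Col1a1 (1.23). The fibroblast list gave a camera adjusted p of 0.0029, and adjusted p = 0.23 with an estimated correlation. Replication-dependent histone genes had 8 rises and 0 falls of 24 (9 and 0 adjusted over the list alone). The histone list gave a camera adjusted p of 0.018, and adjusted p = 0.68 with an estimated correlation, and did not pass without replicate 1 or 2 of every group (adjusted p = 0.113 and 0.482), nor with the stricter low-count filter (adjusted p = 0.071). Pluripotency genes had 1 rise and 6 falls of 30, with Tet2 (-0.50). The pluripotency list gave a camera adjusted p of 0.042, and adjusted p = 0.68 with an estimated correlation, and did not pass without replicate 3 of every group (adjusted p = 0.342), nor with the stricter low-count filter (adjusted p = 0.0803). PRC2 subunits had 0 rises and 4 falls of 11. The PRC2 list gave a camera adjusted p of 0.026, and adjusted p = 0.38 with an estimated correlation, and did not pass without replicate 2 of every group (adjusted p = 0.177). Of the PRC1 genes Pcgf5 (1.10) and Cbx8 (2.57) rose, with 5 rises and 2 falls of 21 (limma camera adjusted p = 0.68). The sum over shRing1b was 2095 genes higher and 1199 lower, 1297 and 85 by at least 2-fold, with the spread taken from all 24 libraries (edgeR quasi-likelihood, two-sided). It depends on that choice: with the shRing1b and shNMC libraries alone 8 genes passed by edgeR, 7 by limma-voom and 1156 by DESeq2. With shRing1b and untransfected libraries alone, which belong to 1 technical set, 0 passed by edgeR, 0 by limma-voom and 355 by DESeq2, while 1626 had an unadjusted edgeR p under 0.05. When the library labelled shRing1b replicate 3 was taken out of this pair, 524 passed by edgeR. All fits against untransfected cells alone, and those on 6 libraries by limma-voom and DESeq2, were chosen after the data were seen. With all 24 libraries and untransfected cells as the control, 1576 genes rose and 883 fell. Without shNMC replicate 1 the sum of 3294 was 2015, and without the library labelled shRing1b replicate 3 it was 4678.

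The hairpin control differed from untransfected mESCs in 1 gene, and that comparison too runs between the technical sets. Atp5j2, which encodes a subunit of the mitochondrial ATP synthase, stood at 107 ± 5.8 CPM with shNMC and 53.1 ± 6.3 CPM without (log2 1.01, SE 0.09, edgeR adjusted p = 6.2e-06, n = 3). It was at 43.9 to 51.3 CPM in the shRing1b libraries, 45.8 to 57.0 CPM in the untransfected ones and 90.1 to 115.6 CPM in the other 18, so it follows the technical set and not the presence of a hairpin. Genes lower with shNMC numbered 0 by edgeR, whereas 608 genes in both directions had an unadjusted edgeR p under 0.05 and DESeq2 called 1 gene. Pou5f1 (-0.07), Nanog (0.08), Sox2 (0.13), Rarb (0.27) and Cyp26a1 (0.43) did not pass. Hoxb1 (-0.43), Gata4 (-0.57), Gata6 (-0.84) and T (-0.47) did not pass either. Camera separated 5 lists with 0 members past the threshold by edgeR or DESeq2, whose median log2 changes were -0.33 (primed-state), 0.25 (germline), -0.27 (immediate early), 0.15 (p53 targets) and -0.43 (extraembryonic endoderm). At an unadjusted edgeR p under 0.05 the members were 3 lower (primed-state), 2 higher (germline), 1 higher (immediate early), 0 (p53 targets) and 1 higher (extraembryonic endoderm), so those of the immediate early and endoderm lists go against the median. The primed-state list gave a camera adjusted p of 4.5e-04, and adjusted p = 0.23 with an estimated correlation. The germline list gave a camera adjusted p of 6.6e-04, and adjusted p = 0.36 with an estimated correlation. The immediate early list gave a camera adjusted p of 6.9e-04, and adjusted p = 0.36 with an estimated correlation, and did not pass without replicate 1 of every group (adjusted p = 0.156). The p53 target list gave a camera adjusted p of 0.0021, and adjusted p = 0.60 with an estimated correlation, and did not pass without replicate 2 or 3 of every group (adjusted p = 0.6 and 0.0548). The extraembryonic endoderm list gave a camera adjusted p of 0.021, and adjusted p = 0.89 with an estimated correlation, and did not pass without replicate 1 or 3 of every group (adjusted p = 0.361 and 0.0502).

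Many genes changed the same way with more than 1 hairpin. In mESCs shMed12 and shRing1b shared 991 rises and 638 falls, against 431.4 and 238.8 from the product of the counts, and 310 genes were opposite. Tcstv1, Zfp352, Krt19 and Hand1 rose and Sox2 fell with both, while the germline genes Sohlh2 and Mael fell with shMed12 and rose with shRing1b. In mESCs shMed12 and shCdk8 shared 233 rises and 141 falls (75.2 and 46.0 from the counts, 61 opposite). After RA they shared 392 and 304 (142 and 122 from the counts, 137 opposite), with Fgf4, Sox2, Phc1 and Aebp2 among the falls and Ddx58 and Oasl2 among the rises. Because each pair shares its shNMC libraries, 100 simulated sets of unchanged groups were compared with the same controls. They shared a mean of 0 calls for shRing1b and of 0.01, at most 1, for each shCdk8 pair. Groups without change yield almost no calls, so these counts do not test the overlap of hairpins that each change genes. The covariance of log2 changes was 0.288 for shMed12 and shRing1b against a mean of 0.0485 in the simulations. For shMed12 and shCdk8 it was 0.155 against 0.0483 in mESCs and 0.122 against 0.0299 after RA. The correlation of log2 changes went the other way: it was 0.383, 0.325 and 0.319 in the same order, below simulated means of 0.458, 0.497 and 0.4996. With shNMC as control for shMed12 and untransfected cells for the other hairpin, 1169 genes were shared with shRing1b (256 opposite) and 461 with shCdk8 (145 opposite). The covariance was then 0.232 and 0.0986, and the correlation 0.317 and 0.183, all below the values with shared controls. The 1629 genes shared with shRing1b were 980 without shNMC replicate 1. The 374 shared with shCdk8 in mESCs were 145, 103 and 172 without shCdk8 replicate 1, 2 and 3, and 114, 153 and 147 without shNMC replicate 1, 2 and 3. The 696 after RA were 419 and 291 without shCdk8 replicate 1 and 2, and 375 and 400 without shNMC replicate 1 and 2.

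Of the named genes that passed, every library of the first group lay beyond every library of the second in the called direction for 95 of 95 with shMed12 in mESCs and 95 of 95 after RA. The same held for 8 of 8 with shCdk8 in mESCs, 53 of 53 after RA, 87 of 90 with RA and 69 of 84 with shRing1b. These genes were counted because they had passed, and those with the largest changes had to be separated to be named, so the counts describe them and test nothing. By camera 65 of 207 list tests passed with the preset correlation and 0 with an estimated one.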

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

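The counts of other splits of the libraries, the range of the Rnf2 share, the genes beyond both sets, the scaling test, the fibroblast test and the RA-course test were chosen only after the results they measure were seen, and the RA-course test was run in 3 forms. All bootstrap bounds below come from resampling genes as if they were independent. They cover the spread between genes and not that between libraries.

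The RA response differed between hairpin and shNMC cells by an interaction test in 820 genes with shMed12 and in 6 with shCdk8. For RA-induced genes with shMed12 the median interaction was -0.58. Named genes with this difference under shMed12 were Gabrp (7.65), Gna14 (3.07), Fgf17 (2.78) and Pou2f3 (2.41), with a more positive response, and Cav1 (-5.03), T (-3.83), Ms4a4d (-3.61) and Otx2 (-3.52), with a more negative one. Under shCdk8 they were Pcdh1 (1.36), Ddx58 (1.13), Sulf1 (1.09), Ptpn13 (0.79) and Klf2 (-1.32). Outside the gene counts, the entry for reads with several alignments held at least 44.1% of all entries in 18 libraries, above the 20.0% to 21.7% of the untransfected and shRing1b libraries, a technical difference whose source the labels do not give.

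The 3294 shRing1b calls were weighed against the technical sets and the library labelled shRing1b replicate 3. Untransfected and shNMC cells differed along these calls by a median of 0.10 on the log2 scale, a share of 0.122 of the median shRing1b change of 0.82, so the difference between the technical sets does not reach the size of the whole pattern. That library differed from the 3 untransfected libraries in 3082 genes, against at most 104 for 1 untransfected library and the other 2, with a lone library assumed to vary like the other groups. This argues against an untransfected library of this series with the wrong label, and libraries 1 and 2 differed in 1293 and 3470 genes by the same test. The fit for the library labelled replicate 3 took it out of the shRing1b group, while the fits for the others kept it there. The shared spread thus differed, and these counts are not fully comparable. The library kept a median share of 0.0763 (95% bootstrap bounds 0.0576 to 0.101) of the shift of libraries 1 and 2, where its Rnf2 loss was a share of 0.267, or 0.0827 to 0.39 with a single untransfected library as the baseline. The spread of Rnf2 in untransfected cells reaches these bounds. In 1870 genes the library lay beyond both the untransfected libraries and libraries 1 and 2, and in 32 between them, which a mixture of such cells alone would not give, but library 2 lay beyond the others in 1536 genes by the same test. A mixture with unsilenced cells thus remains open. A wrong label on a sample from outside the series also remains open, as does weaker silencing of Rnf2 in this library, and in a fit of the compared groups alone 8 genes passed with this library and 2372 without it. The loss of Ring1b, the biological explanation the design names, stays open beside these.

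The weaker RA induction with shMed12 was weighed against scaling and against levels before RA. By edgeR log2 changes the median interaction was -0.63 for the RA-induced genes and 0.05 for the 13678 other genes, a difference of -0.675 (95% bootstrap bounds over genes -0.707 to -0.642). A wrong factor for a whole library would move both sets alike, so scaling of that kind is not the source. Of these genes 838 were not above shNMC before RA in replicate 1, and in replicates 2 and 3 their median interaction was -0.372 (95% bootstrap bounds -0.441 to -0.315), against -0.693 for the 1764 that were above, so levels already raised before RA may account for a part and not for the whole. Of 100 splits 2 gave a median as large, the real one included (-0.575, highest other 0.587), a share under 0.05. Other splits came close (-0.551, 0.535 and 0.526), and 200 splits were possible. The share is thus low, but chance is not excluded by this measure. A role of Med12 in the response to RA, or to the loss of LIF that goes with it, is the biological explanation. It is a hypothesis for genes not raised before RA, from the same data and genes picked in an shNMC-like line.

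The rise of trophectoderm and fibroblast genes with shMed12 was weighed against other cells and against RA-like differentiation. The collagen genes Col1a1, Col1a2 and Col3a1 rose by 9.12, 1.44 and 6.58 CPM where Tagln rose by 270.4 CPM, a median share of 0.0243, and Fn1 fell by 620.6 CPM while Vim rose by 29.1 CPM, which does not decide on fibroblasts among the cells, since their share of collagen transcripts was not measured here and the mESC levels of Fn1 and Vim would hide a small share. Fibroblasts thus remain open, though the labels give feeder-free cultures. For 24 members raised at least 2-fold in replicate 1, the median change with RA in the shCdk8 line was 1.02 on the log2 scale (95% bootstrap bounds 0.81 to 2.23), against 3.50 with shMed12 in replicates 2 and 3. The share of 0.29, with an upper bound of 0.637, left open whether RA reaches much of the change. The change with shMed12 was larger in 23 of the 24, by a median of 2.23 (95% bootstrap bounds 1.13 to 3.26). All were picked for rising with shMed12, so this decides nothing. Hox genes had a median of 0.04 with shMed12 in mESCs against 3.29 with RA. After RA trophectoderm genes were still higher with shMed12 (median 2.67). The 24 h course is thus not the whole cause, and a longer one was not measured. A change of cell state that follows from the loss of Med12 is the biological explanation, and bulk counts leave it untested against growth of a few differentiated cells. Separate clones were not stated, so a property of this shMed12 line other than the loss of Med12 also remains open.

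For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. As large a result came in 1 of 10 splits for shMed12 in mESCs (6594 genes, highest other 0), shRing1b (3294, highest other 1920), shCdk8 in mESCs (596, highest other 0), shMed12 after RA (6814, highest other 0), shCdk8 after RA (1259, highest other 0) and RA (8363, highest other 0). For shNMC against untransfected cells it came in 2 of 10 splits (1 gene, highest other 600).

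For interactions and overlaps 100 splits were drawn. The 820 interaction genes of shMed12 were reached in 13 of 100 splits (highest other 4980) and the 6 of shCdk8 in 13 of 100 (highest other 432), so chance is not excluded for either count by this measure. Of the 12 other splits as large, 11 and 8 regroup the states in opposite ways, which turns the hairpin effect shared by both states into an interaction, and the high counts point to that structure of the samples. The median over RA-induced genes with shCdk8 was matched in 99 of 100 splits (-0.001, highest other 0.286). The overlap of shMed12 and shRing1b (1629 genes) was reached in 6 of 100 splits (highest other 4022), so chance is not excluded, and 4 of the 5 other splits put at least 2 shMed12 libraries in the control group, which makes both comparisons carry the shMed12 effect. The overlaps of shMed12 and shCdk8 were reached in 2 of 100 splits each, in mESCs (374 genes, highest other 4822) and after RA (696 genes, highest other 5020), and the 1 other split in each case has that same structure. Mixing shMed12 with shNMC libraries ended the shMed12 calls (0 genes in every other split of that comparison in either state). A low share can thus follow from the shMed12 effect alone, so it does not test whether the hairpins share genes. With all group labels shuffled, 48 of 100 shuffles gave as many list calls as the real 65 (33 to 87 in the shuffles, median 64), so chance is not excluded for the number of list calls with the preset correlation.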

How the results depend on the processing

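Limma voom with sample weights, fits without the library labelled shRing1b replicate 3 except the planned one of shRing1b against shNMC over all groups, the shRing1b fits on the compared groups alone except planned edgeR against shNMC, and the overlaps on the compared groups alone were chosen only after the data were seen.

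Counts of genes moved by more than 1.5 times as follows, and the cause was not tested. The count for shRing1b (3294) was 8 from the compared groups alone by edgeR, 7 by limma voom and 1156 by DESeq2. Against untransfected cells alone it was 0 by edgeR, where 1626 genes had an unadjusted p under 0.05, 0 by limma voom and 355 by DESeq2, and 524 by edgeR less the library labelled shRing1b replicate 3. For shCdk8 in mESCs (596) it was 1151 by DESeq2, 2334 from the compared groups alone and 992 with untransfected cells as control, and for shCdk8 after RA (1259) 2744 from the compared groups alone. The 1 gene between shNMC and untransfected cells became 0 by edgeR from the compared groups alone, where 422 of 14382 genes tested had an unadjusted p under 0.05. The interaction of shMed12 (820) gave 1250 genes by DESeq2 and 2237 from the compared groups alone, and that of shCdk8 (6) 27 and 38. Overlaps from the compared groups alone were 546 for shMed12 and shRing1b (1629), 1450 for shMed12 and shCdk8 in mESCs (374, and 659 by DESeq2) and 1762 after RA (696). With voom and sample weights the counts were 10421 and 10346 for shMed12 in mESCs and after RA, 5288 and 6396 for shCdk8, and 5692 and 803 for the interactions of shMed12 and shCdk8.

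With the replicate number as a block the count was 905 for shCdk8 in mESCs and 11 for the shCdk8 interaction, and within 1.5 times of the reported count for the other comparisons and overlaps run.

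Leaving out 1 library at a time gave 2015 to 4678 genes for shRing1b, 170 to 1350 for shCdk8 in mESCs, 482 to 2264 for shCdk8 after RA, 489 to 1471 for the shMed12 interaction and 3 to 16 for that of shCdk8. Overlaps were 980 to 2440, 103 to 332 and 291 to 598 in the order above. The highest values for single comparisons and interactions were those without the library labelled shRing1b replicate 3. Outside the shRing1b comparison it enters only through the shared spread, whose size with and without it was not compared. The median of RA-induced genes with shCdk8, close to 0 as reported, was -0.0567 to 0.0814, 0.0700 for genes with a log2 change of at least 2 and -0.101 for genes defined in shNMC cells. With shMed12 that median was -0.66 to -0.56, and -0.84 to -0.57 under the other settings.

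Of 65 list calls 0 held with an estimated correlation, 64 with median-ratio scaling, 63 with the stricter filter, 65 with the block and 56, 53 and 59 without replicate 1, 2 and 3 of every group, with 0 changes of direction. Calls gained were 0, 0, 5, 5, 8, 3 and 16 in the same order. Of 475 called results of named genes 0 were lost with median-ratio scaling, 2 with the block, 3 of 474 by DESeq2 and 90 when any single library was left out, and 0 were reversed.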

Other observations

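The genes and gene types of this part were chosen after their values were seen, and their p-values were not adjusted for that choice.

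Imprinted transcripts of the Meg3 cluster were higher with shMed12: log2 changes were 0.74 for Meg3, 0.60 for Rian and 1.06 for Mirg in mESCs, and 1.33, 1.23 and 1.61 after RA. With shCdk8 Mirg was higher in mESCs (0.88), where Meg3 (0.46) and Rian (0.51) did not pass, and all 3 were higher after RA (0.80, 0.80 and 0.99), and with RA in shNMC cells they fell (-1.19, -1.11 and -1.23). H19 rose with shMed12 (1.16 in mESCs and 2.78 after RA, interaction 1.62) and fell with shCdk8 (-1.07 and -0.97). Vax2os2 fell with shMed12 (-3.62 in mESCs, -4.38 after RA), with shCdk8 (-0.92 and -1.56) and with RA (-2.94). Of 12 small nucleolar RNA hosts tested (Gas5 and the Snhg genes) 8 fell with RA, among them Gas5 (-0.88), Snhg12 (-0.96) and Snhg5 (-0.90), Snhg11 rose (0.70) and 3 did not pass.

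By gene type, matched for 99.3% of the 16280 genes, 470 are long non-coding and 15420 protein-coding. With RA 133 long non-coding genes rose and 71 fell, against 4245 and 3768 coding genes. With shRing1b they were 49 and 13 against 2014 and 1168. With shMed12 they were 70 and 72 against 3233 and 3132 in mESCs and 58 and 106 against 3360 and 3198 after RA, and with shCdk8 5 and 4 against 355 and 224 and 12 and 19 against 650 and 566. Their median abundance is 0.843 CPM against 21.2 CPM, and no test matched for abundance was run.

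The library labelled shRing1b replicate 3 stands apart in genes other than Rnf2. In libraries 1, 2 and 3 of shRing1b Adm stood at 0.674, 1.30 and 15.4 CPM, Bnip3 at 34.6, 35.2 and 231 CPM and Stc1 at 0.775, 1.77 and 11.8 CPM. Untransfected libraries held 0.359 to 3.63 CPM of Adm and 40.4 to 57.0 CPM of Bnip3, and at most 1.74 CPM of Stc1. These genes are often raised at low oxygen, but no measure of culture conditions is given. Dnajc2, the gene of the Zrf1 protein named in the series text, was at 158, 155 and 139 CPM in these libraries against 148 to 178 CPM in untransfected cells.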
